A study of Mus musculus with 2 samples.

How the data were processed

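Adrenal gland tissue of 25-day-old male mice was profiled by long-read RNA sequencing of total RNA in 2 libraries, which the labels number as replicates 1 and 2 of 1 group. The library descriptions name the same animal for both, the tissue descriptions name different animals, and both carry the same donor record, so it is unclear whether they are separate animals. RNA input is given for replicate 2 alone (1 µg). The labels name Lexogen spike-ins and an Ambion mix. In the tables analysed here the spike-in reads were all ERCC RNAs, and SIRV molecules are not analysed here.

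Read counts per transcript model were deposited by the authors for each library separately, not normalised, with a transcript annotation for each. Per the file headers the assembly is mm10 and the annotation GENCODE M21, and attribute names in the annotation files are those of TALON. The aligner and the versions of the tools are not given in the sources used here. Every model carries a class from the authors: known, incomplete splice match (ISM), NIC, NNC, genomic, antisense or intergenic. Models called in each library separately have their own identifiers, so models were matched between libraries by strand and intron chain. In the deposited annotations 19364 of 19372 quantified annotated transcripts of replicate 1, and 21256 of 21262 of replicate 2, had the exons of the reference GENCODE M21 file, and the other 8 and 6 lay on sequences with other names. Gene coordinates are those of GENCODE M21.

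Counts of all models of a gene were summed, and CPM was computed over reads in annotated mouse genes (752432 and 1210671), leaving out spike-ins (11058 and 17139 reads, 1.39% and 1.33% of all reads) and loci outside annotated genes (30509 and 62532 reads, 3.84% and 4.85%). No length correction was made, since a long read counts a molecule. The files held 104489 and 140263 models, of which 63.7% and 61.6% had a single read, and 15242 and 16852 genes. Protein-coding genes took 97.9% and 97.7% of gene reads, and the 10 most abundant genes 8.83% and 10.4%. Whether reads of PCR copies were merged is not given in the sources used here, so intervals and limits (95% Clopper-Pearson, 3 reads for a count of 0) cover counting error only.

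The gene lists, tests, named-gene rule and first set of alternatives were fixed before the data were examined. The 19 lists were steroidogenesis, cholesterol supply, zona glomerulosa, zona fasciculata, X-zone, chromaffin cell, Schwann and sustentacular cell, capsule and stroma, endothelial, macrophage and leukocyte, erythroid, adipocyte, kidney, liver, proliferation, immediate early, antioxidant, imprinted and sex-linked genes, with 2 more by symbol, the mitochondrially encoded and the cytosolic ribosomal protein genes. Lists of 40 liver and 28 skeletal muscle transcripts were added later for the tests of the closing section. Named genes are the 10 nuclear genes with the highest mean CPM, the 10 highest of the steroidogenesis and chromaffin lists, and the 4 highest of each other list. Cyp11b2, Cyp17a1, Xist and the Y-linked genes are always given. The rule also takes the 5 genes with the largest ratio between libraries in each direction with at least 20 reads. For isoforms it takes the 8 most abundant genes whose leading model holds under 50% with at least 100 reads in each library, the 8 NIC or NNC chains with the most reads, and the 5 intergenic and 5 antisense loci with the most reads. Any steroidogenesis or chromaffin gene with at least 100 reads in each library may also be given the share of its leading model. Some genes that the rule takes are not reported here. Genes named outside it are said to be chosen after their values were seen. Genes with near-identical copies are given as uncertain.

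With 1 group, nothing was tested between conditions. A list's median log2 level (pseudocount 1 CPM) was placed among 10000 random lists of the same size drawn from all detected genes and undetected list members. Genes were compared between libraries by Fisher's exact test (two-sided) on reads against all other reads, for genes with at least 10 reads in both libraries together, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 ratios used a prior of 0.5 reads, and a gene with 0 reads in a library was given a bound from 3 reads. Dispersion came from edgeR with an intercept alone. Isoform use was compared in genes with at least 20 reads in each library and 2 or more chains of at least 5 reads, by a chi-square statistic with 10000 permutations of reads, or Fisher's exact test for 2 chains. Recurrence used multi-exon chains with at least 2 reads.

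Alternatives were TMM and DESeq2 scaling, leaving out mitochondrial genes, known transcripts alone, leaving out genomic or ISM reads, other read minimums and pseudocounts, thinning the deeper library, matching splice sites within 5 bp, an assumed coefficient of variation of 0.2, and leaving out each library. Leaving out genes over 10-fold different between libraries or the most abundant member of a list, and taking chains with exactly 2 to 4 reads, were chosen after seeing the data. Both statistical scripts were tested on simulated data. In the comparison of reads per gene (11367 genes tested), 41.0% of 100 genes changed 2-fold and 88.0% of 100 changed 4-fold were recovered, 86.8% and 100% among those with at least 100 reads, with 3 false calls. In the comparison of isoform use (3437 genes tested), 95.5% of 200 genes with a shift of 30 percentage points were recovered, with 7 false calls. Both simulations held counting noise alone, which is the noise the tests assume, so few false calls were built in. They do not show how many calls between the real libraries reflect other variation between libraries. No genome sequence was used here, so priming at internal A stretches and splice-site motifs were not examined. Computation used R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.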

Results

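Long-read RNA sequencing was applied to adrenal gland tissue of male mice aged 25 days of the hybrid strain B6CASTF1/J, the offspring of C57BL/6 and CAST/EiJ parents. The labels place both libraries in 1 group, as replicates 1 and 2, so no condition was compared with another. The questions the design allows are which transcripts this endocrine gland held, how far the libraries differed, and which transcript structures recurred. The deposited tables gave 793999 reads in replicate 1 and 1290342 in replicate 2, of which 752432 and 1210671 lay in annotated mouse genes. Levels are reads per 1000000 of those gene reads (CPM), and 3 reads, the limit that a count of 0 allows, correspond to 3.99 CPM in replicate 1 and 2.48 CPM in replicate 2. A gene level written with ± is the mean and SD over n = 2 libraries, and a log2 ratio of replicate 2 to replicate 1 carries its counting standard error (SE). The labels do not show clearly that the libraries came from separate animals, so this spread may be technical. Intervals, standard errors and limits cover counting error only. Tests between the libraries compare 2 libraries, not conditions, and used Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over 11382 genes.

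Genes of steroid hormone synthesis were among the most abundant nuclear-encoded genes. Cyp11a1, which cleaves the cholesterol side chain (chromosome 9, 58006411 to 58027023, mm10), had the highest mean level of the 2 libraries, 14396 ± 7651 CPM; it ranked 1 in replicate 1 and 5 in replicate 2, behind Trf, Alb, Apoe and Serpina3k. Cyp21a1, the 21-hydroxylase, reached 8710 ± 6355 CPM, Cyp11b1, the 11β-hydroxylase that completes corticosterone synthesis (chromosome 15, 74834125 to 74841643), 7353 ± 5641 CPM, Star, which delivers cholesterol to the inner mitochondrial membrane (chromosome 8, 25806555 to 25815982), 6434 ± 3163 CPM, and Hsd3b1 5895 ± 2775 CPM. The 22 listed genes of steroidogenesis were all detected in both libraries and summed to 49615 ± 28295 CPM, 6.96% of gene reads in replicate 1 and 2.96% in replicate 2. Their median level lay at percentile 100 among 10000 random lists of the same size.

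The next members of the list were Akr1b7, an aldo-keto reductase (2253 ± 1657 CPM), the electron donors Fdxr (985 ± 136 CPM) and Fdx1 (615 ± 131 CPM), Cyb5b (523 ± 385 CPM) and the aldosterone synthase Cyp11b2 (chromosome 15, 74851010 to 74856318; 437 ± 257 CPM). Cyp17a1, the 17α-hydroxylase that mouse adrenal cortex largely lacks after birth, had 6 and 9 reads, 7.70 ± 0.382 CPM. Of 21 members tested, 15 were lower and 2 higher in replicate 2, and the numbers were 15 and 2 when adjusted over the list alone. With TMM factors or DESeq2 size factors 10 were lower and 3 higher. Cyp11b1 had a log2 ratio of -1.75 ± 0.03 (SE), Cyp21a1 -1.65 ± 0.02 and Cyp11a1 -1.14 ± 0.02, and the members higher in replicate 2 were Cyb5a and Hsd11b1 (named after their values were seen). The 6 genes of the liver list summed to 2.66 CPM in replicate 1 and 29162 CPM in replicate 2, in which the steroidogenic sum was lower. In an alternative chosen after seeing the data, genes over 10-fold different between the libraries were left out of the total. The steroidogenic sum was then 70373 CPM in replicate 1 and 38336 CPM in replicate 2, still lower in replicate 2. Cyp21a1 has a pseudogene and Hsd3b1 close paralogs, so their levels are uncertain to the extent that reads were shared.

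Markers of the cortical zones were present at unequal levels. The 4 listed genes of the zona fasciculata, the glucocorticoid-producing zone, all of which also stand in the steroidogenesis list, summed to 15174 CPM in replicate 1 and 4624 CPM in replicate 2 (percentile 100). Among them, Mrap, the accessory protein of the ACTH receptor, had 245 ± 173 CPM and the receptor Mc2r 47.6 ± 10.9 CPM. The level of Mc2r is uncertain, since it leaves out 57 and 84 reads of an antisense chain at the gene. All introns of that chain coincide with annotated introns on the opposite strand. In the zona glomerulosa list (11 genes, 4317 and 1480 CPM, percentile 98.5) the potassium channel gene Kcnk3 led with 1578 ± 1046 CPM, followed by Cyp11b2, Dab2 (331 ± 412 CPM) and Wnt4 (249 ± 36.2 CPM). Akr1c18, the 20α-hydroxysteroid dehydrogenase that marks the transient X-zone next to the medulla, had 877 ± 963 CPM, while Thrb and Pik3c2g, the other X-zone genes, had 13.7 ± 8.84 and 7.47 ± 8.23 CPM, and the median of this list lay at percentile 55.0. The ratio of Cyp11b1 to Cyp11b2 reads was 18.3 in replicate 1 (95% Clopper-Pearson interval 16.7 to 20.1) and 13.2 in replicate 2 (11.7 to 14.8), and that of Cyp11b1 to Akr1c18 was 7.28 (6.85 to 7.75) and 17.2 (15.1 to 19.7). The ratio of Hsd3b1 to its glomerulosa paralog Hsd3b6 was 116 (88.0 to 156) and 106 (78.9 to 145).

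The sum of each zone list was lower in replicate 2, the library with 29162 CPM of liver-list reads. In the fasciculata list 3 of 4 genes were lower and 0 higher (3 and 0 adjusted over the list alone; 3 and 1 with either other scaling). In the glomerulosa list 7 of 11 were lower and 0 higher (9 and 0 adjusted over the list alone; 5 and 0 with either scaling), with Dab2 at a log2 ratio of -3.96 ± 0.22 (SE). In the X-zone list 2 of 3 were lower and 0 higher (3 and 0 adjusted over the list alone; 2 and 0 with either scaling), and Akr1c18 was 7.96-fold lower in replicate 2 (adjusted p = 1.10e-260, Fisher's exact test). For single genes a scaling matters most near no change, since TMM placed no change at a log2 ratio of -0.35 and size factors at -0.40.

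The 24 genes of cholesterol synthesis, uptake and storage summed to 8434 CPM in replicate 1 and 21244 CPM in replicate 2 (percentile 100), beside 2.66 and 29162 CPM of the liver list. The higher sum of replicate 2 came from Apoe alone, since the other 23 genes summed to 6770 and 4343 CPM, an alternative chosen after seeing the data. Apoe, a lipoprotein component that liver also makes in quantity, had 1664 and 16900 CPM, a log2 ratio of 3.34 ± 0.04 (SE). Scarb1, the HDL receptor through which mouse adrenal cells take up cholesteryl esters, had 1509 ± 786 CPM, Hmgcs1 of the mevalonate pathway 685 ± 76.9 CPM and the cholesterol esterifying enzyme Soat1 558 ± 498 CPM. Of 24 genes tested, 6 were higher and 7 lower in replicate 2 (6 and 7 adjusted over the list alone). The balance turned to 8 higher and 3 lower with TMM and to 9 and 3 with size factors, and the median log2 ratio from -0.08 to 0.26 and 0.32. Abcb1b, a drug efflux transporter gene outside the lists, was among the 10 most abundant genes with 5246 ± 3439 CPM.

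The adrenal medulla was represented by 31 chromaffin cell genes, of which 30 were detected in both libraries, at 10807 ± 2890 CPM in sum (percentile 98.7). The granins led, with Chgb (chromosome 2, 132781278 to 132795079) at 3870 ± 783 CPM, Chga at 2737 ± 191 CPM and Scg2 at 1398 ± 984 CPM. Th, the rate-limiting enzyme of catecholamine synthesis (chromosome 7, 142892752 to 142931128), had 1309 ± 517 CPM. Pnmt, which makes adrenaline from noradrenaline, had 206 ± 50.1 CPM, Dbh, the dopamine β-hydroxylase, 140 ± 83.7 CPM, and the granule cytochrome gene Cyb561 468 ± 126 CPM. The neuropeptide gene Npy had 154 ± 4.01 CPM, Pcsk1n 70.8 ± 8.95 CPM and the transcription factor gene Gata2 51.6 ± 19.2 CPM.

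Of 28 chromaffin genes tested, 13 were lower in replicate 2, 1 (Ddc, chosen after its value was seen) was higher and 14 were not called. Adjusted over the list alone the numbers were 13 and 1. They fell to 5 lower and 2 higher with TMM and to 4 and 2 with size factors. Scg2 had a log2 ratio of -1.58 ± 0.06 (SE) and Th of -0.83 ± 0.06, while Chga, called lower at -0.14 ± 0.04, lay on the other side of no change with both scalings. The list summed to 12850 CPM in replicate 1 and 8764 CPM in replicate 2, beside 2.66 and 29162 CPM of the liver list. With genes over 10-fold different between the libraries left out of the total, the sums lay closer, at 12989 and 11347 CPM. The genes left out held more of the reads of replicate 2, so this alternative raises its levels more by construction. The ratio of Th to Pnmt reads was 6.92 (95% Clopper-Pearson interval 5.92 to 8.13) and 5.52 (4.76 to 6.43). These intervals overlapped, which does not show that the ratios were equal, and their difference was not tested. The ratio of Chgb to Chga was 1.54 (1.46 to 1.63) and 1.27 (1.22 to 1.34), and that of the steroidogenic to the chromaffin sum 5.42 (5.30 to 5.54) and 3.38 (3.31 to 3.45), so that both ratios differed by more than counting error.

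**Figure D1:**
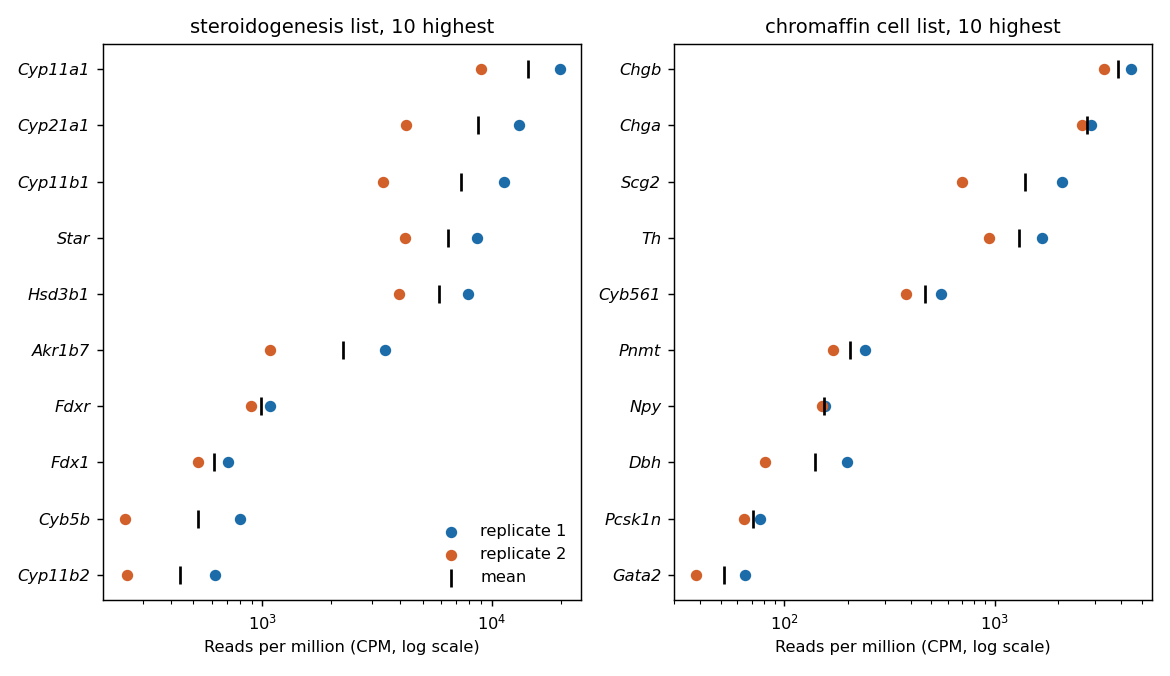
Level in CPM, on a log axis, of the 10 genes with the highest mean in the steroidogenesis list and in the chromaffin cell list, with a point for each of the 2 libraries and a bar at their mean. Cyp11a1 lies at 19806 CPM in replicate 1 and 8986 CPM in replicate 2, and Chgb at 4424 and 3316 CPM; these ratios are on total-read scaling.

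Supporting cell types were present at lower levels. Capsule and stroma genes (11 genes, 1350 ± 264 CPM, percentile 96.1) were led by the collagen gene Col3a1 at 694 ± 36.8 CPM, with Dcn at 200 ± 63.1, Col1a1 at 199 ± 59.1 and Col1a2 at 77.3 ± 33.5 CPM. Endothelial genes (11 genes, 789 ± 123 CPM, percentile 98.2) were led by Plvap, a component of the diaphragms of fenestrated capillaries, at 262 ± 88.0 CPM, with Cldn5 at 121 ± 7.60, Egfl7 at 103 ± 19.4 and Tie1 at 77.1 ± 20.7 CPM. Macrophage and leukocyte genes (15 genes, 468 ± 56.6 CPM, percentile 77.8) included Cd74 at 107 ± 14.3, Lyz2 at 98.0 ± 13.6, H2-Ab1 at 49.8 ± 25.3 and C1qb at 49.7 ± 4.49 CPM. Schwann and sustentacular cell genes (9 genes) reached 39.7 ± 3.47 CPM (percentile 3.71), with S100b at 16.7 ± 2.64, Erbb3 at 9.18 ± 9.22 and Mbp at 6.63 ± 0.0263 CPM.

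Globin and fat transcripts were abundant as well. Hba-a1 had 1262 ± 61.1, Hbb-bs 723 ± 26.2, Hba-a2 314 ± 4.96 and Hbb-bt 152 ± 30.6 CPM, values that near-identical copies make uncertain between the copies, and the erythroid list of 6 genes summed to 2542 ± 94.6 CPM (percentile 100). Adipocyte genes (8 genes, 3178 ± 792 CPM, percentile 100) were led by Cidea at 710 ± 93.8 CPM, with Fabp4 at 673 ± 448, Cfd (adipsin) at 634 ± 29.9 and Ucp1, the uncoupling protein of brown fat, at 629 ± 214 CPM. Of the 7 kidney genes 6 had no read in either library and Aqp2 had 2 reads in replicate 2.

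Between the libraries, 5 of 10 tested stromal genes were lower in replicate 2 (5 adjusted over the list alone), with 0 higher, against 2 lower and 1 higher with TMM and 1 and 1 with size factors. For endothelial genes 4 of 11 were lower and 0 higher (4 and 0 adjusted over the list alone), but 1 lower and 3 higher with TMM and 0 and 3 with size factors. For adipocyte genes 3 of 8 were lower and 0 higher (3 and 0 adjusted over the list alone), but 2 and 2 with TMM and 2 lower and 3 higher with size factors. Macrophage genes were higher in 2 of 11 (2 adjusted over the list alone; 4 with either scaling), erythroid genes in 1 of 5 (2 adjusted over the list alone; 5 with either scaling) and Schwann cell genes in 1 of 3 (1 adjusted over the list alone; 1 with either scaling), with 0 lower in these 3 lists. Replicate 2, in which these differences were read, held 29162 CPM of liver-list reads. The skeletal muscle list, added later, summed to 5137 CPM in replicate 1 and 81.8 CPM in replicate 2. The adipocyte sum was 3739 CPM in replicate 1 and 2618 CPM in replicate 2. With genes over 10-fold different between the libraries left out of the total, it was 3779 and 3390 CPM. That alternative raises the levels of replicate 2 more by construction.

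Among regulated gene groups, antioxidant genes (12 genes, 4599 ± 168 CPM, percentile 100) included catalase (Cat) at 940 ± 382, Gpx3 at 574 ± 348, and the mitochondrial proteins' genes Prdx3 at 562 ± 260 and Txn2 at 552 ± 111 CPM. In replicate 2, 5 of 12 were higher and 4 lower (5 and 5 adjusted over the list alone), against 7 higher and 2 lower of 13 gene records with either scaling, Nnt being 2 records. Imprinted genes (23 genes, 3817 ± 563 CPM, percentile 82.3) were led by Gnas at 1795 ± 47.9 CPM, with Cdkn1c at 984 ± 321, Dlk1 at 305 ± 136 and Ndn at 243 ± 75.8 CPM. Of 15 tested, 9 were lower and 2 higher in replicate 2 (9 and 3 adjusted over the list alone; 7 and 5 with either scaling). Immediate early genes (13 genes, 520 ± 199 CPM, percentile 54.8) included Jun at 191 ± 126, Ier2 at 92.4 ± 32.9, Junb at 85.1 ± 15.1 and Nr4a1 at 64.4 ± 66.6 CPM, with 3 of 9 higher and 1 lower in replicate 2 (3 and 1 adjusted over the list alone; 5 and 1 with either scaling). Proliferation genes (10 genes, 329 ± 72.5 CPM, percentile 72.4) were led by Mcm2 at 120 ± 44.6, Rrm2 at 53.3 ± 1.73, Mcm5 at 48.3 ± 18.1 and Pcna at 40.4 ± 8.27 CPM. Of 9 tested, 2 (Mcm2 and Mcm5) were lower in replicate 2 and 1 was when adjusted over the list alone, 0 lower and 0 higher with TMM, and 0 lower and 1 higher with size factors. These differences again went with 29162 CPM of liver-list reads in replicate 2.

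Y-linked genes were detected in both libraries, which are labelled male. Ddx3y had 91.2 ± 15.7, Eif2s3y 72.2 ± 23.8, Uty 22.1 ± 10.2 and Kdm5d 6.97 ± 5.18 CPM, and Xist, the RNA of the inactive X chromosome, had 0 reads in both libraries, which allows up to 3.99 CPM in replicate 1 and 2.48 CPM in replicate 2. Of 4 sex-linked genes tested, 1 (Eif2s3y) was lower in replicate 2 (1 adjusted over the list alone; 0 with either scaling). Mitochondrially encoded genes (37 genes, 959 ± 194 CPM, percentile 0) were led by mt-Co1 at 424 ± 259 CPM, with mt-Rnr2 at 119 ± 110, mt-Cytb at 118 ± 34.6 and mt-Nd2 at 60.3 ± 10.5 CPM. Reads were found for 12 of the 37 in replicate 1 and 19 in replicate 2, and the median of their mean levels was 0.413 CPM. The percentile is that of this median and does not describe the sum. Of 11 tested, 4 were lower and 2 higher in replicate 2 (4 and 2 adjusted over the list alone), 3 and 3 with TMM and 2 and 3 with size factors. Cytosolic ribosomal protein genes (83 genes, 13007 ± 1269 CPM, percentile 100) included Rpl4 at 656 ± 8.87, Rplp0 at 645 ± 19.7 and Rpl3 at 603 ± 85.2 CPM. Of 80 tested, 26 were higher and 2 lower in replicate 2 (26 and 2 adjusted over the list alone), 59 and 1 with TMM and 65 and 1 with size factors, beside the liver list at 29162 CPM there.

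The libraries differed most in transcripts of liver and of skeletal muscle. Alb, serum albumin (chromosome 5, 90460897 to 90476602), had 2 reads in replicate 1 and 21951 in replicate 2, a 6821-fold ratio (95% counting interval 1888 to 56329), and Serpina3k 2 and 14654 reads, a 4554-fold ratio (1260 to 37605). Transferrin (Trf) had 219 and 26314 CPM. With 0 reads in replicate 1, Apoa1 was at least 1039-fold, Ahsg at least 963-fold, Gc at least 901-fold and Mup3 at least 897-fold higher in replicate 2, against a limit of 3 reads per library. All 6 genes of the liver list, Ttr and Fgb among them, were higher in replicate 2 (6 adjusted over the list alone; 6 with either scaling). In the other direction, the muscle genes Atp2a1 (1552 CPM), Acta1 (1209 CPM), Ckm (849 CPM), Tnnc2 (161 CPM) and Myh1 (128 CPM) in replicate 1 had 0 reads in replicate 2, at least 626-fold, 488-fold, 343-fold, 64.9-fold and 51.5-fold lower.

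Across 18168 genes detected in either library, of which 13926 were detected in both, the log2 levels had a Pearson correlation of 0.808 and a Spearman correlation of 0.813; genes are not independent replicates. The coefficient of variation that edgeR terms biological was 0.604, a spread that may be technical here. It was 0.374 without genes over 10-fold different between the libraries, an alternative chosen after seeing the data. Those genes were picked by the ratio between these libraries, so a lower spread was built in. A chi-square over genes of 322329 on 11381 degrees of freedom, 28.3 per degree, exceeded sampling noise, so the libraries were counted as 2; such a test also responds to differences in preparation. Of 11382 genes tested, 4183 (36.8%) were called, 1307 higher and 2876 lower in replicate 2, and 2780 of the called genes differed by over 2-fold. The split was 2015 higher and 1563 lower with TMM, and 2192 and 1387 with size factors. Genes over 10-fold higher in replicate 2 numbered 538 and held 22.8% of its gene reads, against 0.317% in replicate 1, and 80 genes over 10-fold lower held 0.750% of the reads of replicate 1. Without these genes, an alternative chosen after seeing the data, 2846 genes were called, 1452 higher and 1394 lower. Part of this fall was built in, since the genes left out were picked by the same ratio. With an assumed coefficient of variation of 0.2 in place of counting noise alone, the exact test of edgeR called 1523. The assumed value is below the estimates of 0.604 and 0.374, so 1523 does not allow for the full spread between these libraries.

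**Figure D2:**
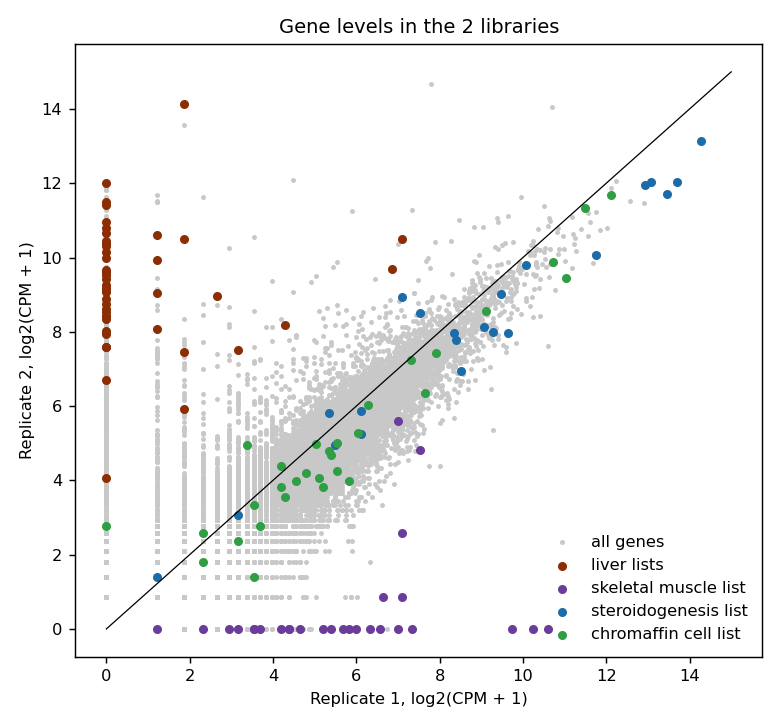
Level of each gene in replicate 2 against replicate 1, in log2(CPM + 1), with the genes of the liver, skeletal muscle, steroidogenesis and chromaffin cell lists coloured and the line of equal levels drawn. Alb lies at 2.66 CPM in replicate 1 and 18131 CPM in replicate 2, Cyp11a1 at 19806 and 8986 CPM, and Atp2a1 at 1552 and 0 CPM.

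Most reads belonged to annotated transcripts. The known class held 74.0% of mouse reads in replicate 1 (95% Clopper-Pearson interval 73.9 to 74.1) and 71.9% in replicate 2 (71.8 to 72.0), 72.9% ± 1.49 on average (SD, n = 2). Incomplete splice matches (ISM), which match part of the structure of an annotated transcript, took 9.09% and 11.3%. Models with a single exon, and so no intron, were 10.7% and 15.3% of ISM reads. Chains that combine annotated splice sites in a way outside the annotation (NIC) took 5.45% and 4.08%, and chains with a splice site outside it (NNC) 3.99% and 3.10%. The genomic class took 3.73% and 4.89%, antisense 3.32% and 4.24%, and intergenic 0.440% and 0.472%. Single-exon models made up 97.7% and 98.1% of genomic reads and 96.6% and 97.3% of antisense reads. The lower known share and the higher antisense share of replicate 2 exceeded counting error (Fisher's exact test, two-sided, p = 1.31e-238 and 1.92e-245), in the library whose liver list reached 29162 CPM. With multi-exon models alone the known share was 80.001% in replicate 1 and 80.148% in replicate 2, so the lower share of replicate 2 was lost and its direction turned, and the antisense share was 0.126% and 0.132%. The ISM share was still higher in replicate 2, at 9.11% and 11.2%, while NIC (6.12% and 4.76%) and NNC (4.49% and 3.62%) were lower. Among gene groups, the known share was 70.2% and 61.9% of steroidogenesis reads, with 8.75% and 13.8% in the genomic class. It was 85.0% and 82.7% of chromaffin reads, 68.2% and 77.8% of adipocyte reads, and 79.5% of the liver-list reads of replicate 2.

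Recurrence between the libraries differed by class. Of known multi-exon chains with at least 2 reads, 91.2% of those in replicate 1 were present in replicate 2, and 85.9% in the opposite direction. The shares were 71.0% and 48.1% for ISM, 66.7% and 60.5% for NIC, and 59.3% and 46.0% for NNC. The difference between directions depended on depth, since replicate 2 held more reads. With replicate 2 thinned to the total of replicate 1, the shares were 86.8% and 88.7% for known and 61.2% and 52.8% for ISM chains. They were 56.6% and 66.3% for NIC and 49.4% and 50.7% for NNC, so the direction turned for known, NIC and NNC chains. The tests below used all reads. NIC chains recurred more often than NNC chains in both directions (Fisher's exact test, two-sided, p = 3.92e-11 and 7.58e-43), whereas ISM chains recurred more often than NIC chains from replicate 1 (p = 3.82e-07, Fisher's exact test) and less often from replicate 2 (p = 1.19e-54, Fisher's exact test). The order of NIC and NNC turned from replicate 1 when splice sites within 5 bp were matched (70.7% for NIC and 72.4% for NNC) and with at least 10 reads (97.6% and 98.3%). From replicate 2 it stayed, at 63.4% and 57.4% within 5 bp and 83.7% and 71.0% with at least 10 reads. Multi-exon antisense, genomic and intergenic chains were few, with 65 antisense chains from replicate 1 (69.2% recovered) and 141 from replicate 2 (41.8%). In a comparison chosen after the values were seen, 48.9% and 50.1% of multi-exon antisense reads lay in chains whose introns all coincided with annotated introns on the opposite strand.

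**Figure D3:**
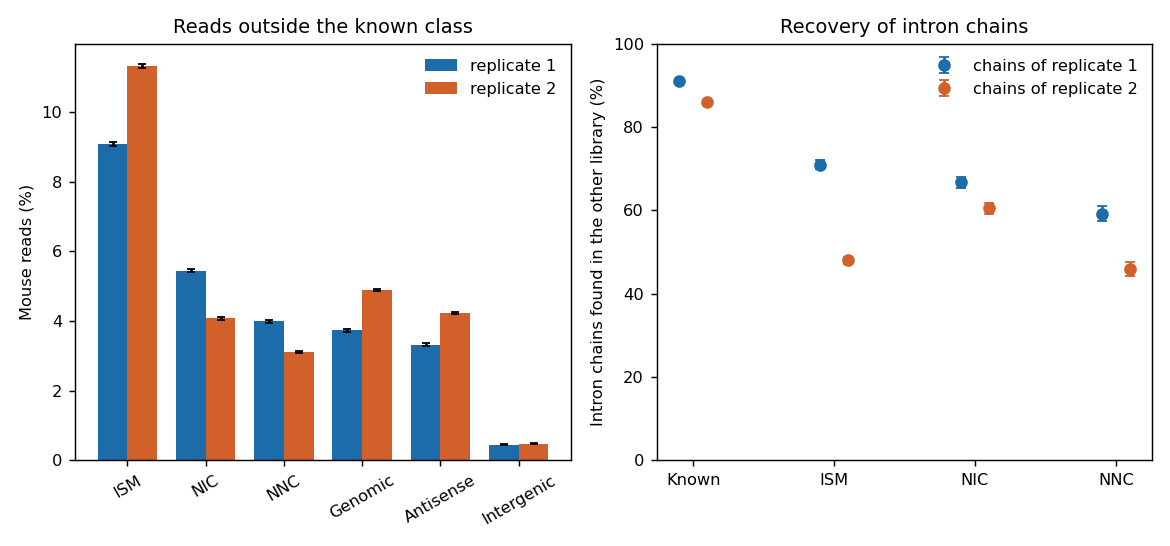
Bars give the percent of mouse reads in each class outside the known class for both libraries, and points the percent of multi-exon intron chains with at least 2 reads that were found in the other library, all with 95% Clopper-Pearson intervals. ISM took 9.09% and 11.3% of reads, and known chains recurred in 91.2% and 85.9%, NNC chains in 59.3% and 46.0%. Neither library was thinned.

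For most genes a single transcript model held the bulk of reads. Over 5749 genes with at least 20 reads in each library, the median share of the leading model was 76.6% in replicate 1 and 70.8% in replicate 2 (73.7% ± 4.05, SD, n = 2), and 971 genes (16.9%) lay under 50% in both. The leading chain was the same in 4825 genes and another in 429, with 495 led by a single-exon model in either library. Akr1b7 had 95.6% and 93.7% of its reads in the annotated leading transcript, Th 92.0% and 86.4%, Cyp11b1 90.9% and 83.2%, Chgb 86.7% and 92.1%, Cyp21a1 84.8% and 77.9%, Star 80.1% and 77.9%, and Cyp11a1 64.8% and 55.8%. For Hsd3b1 an ISM model with 4 exons led with 79.9% and 78.8%. For Nr5a1, the steroidogenic transcription factor gene, a known model led in replicate 1 (46.3%) and an ISM model in replicate 2 (44.1%). Among the most abundant genes under 50% in both were Hadhb (47.1% and 48.2%), Scg2 (47.7% and 48.9%), Ddx5 (43.9% and 42.0%), Fasn (14.4% and 20.4%), Cdkn1c (31.1% and 32.1%), Chpt1 (36.4% and 36.2%) and Cnbp (44.7% and 46.5%). In Ddx5, Fasn and Chpt1 the leading model was not the same in both libraries, so their shares are of different transcripts. These shares rest on reads of every class, and with known transcripts alone the median was 98.9% and 53 of 4266 genes lay under 50%.

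Isoform use differed between the libraries in 553 of 3172 genes tested (17.4%; permutation test of reads, or Fisher's exact test for genes with 2 chains, adjusted p under 0.05), with a median largest shift of 17.5 percentage points in called genes and 5.40 in the others. Cyp11a1, Cyp21a1, Cyp11b1, Star, Chgb, Chga and Th were called, each at the smallest adjusted p reached, 0.00139, which the number of permutations limits. Hsd11b1 was called too, with its leading transcript at 58.8% in replicate 1 and 81.8% in replicate 2, while Pnmt (92.3% and 93.7%) and Cyp11b2 (88.2% and 86.1%) were not called. With known transcripts alone 89 of 1527 genes tested were called, and with ISM reads left out 131 of 2482.

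Several chains outside the annotation were abundant in both libraries. Oaz1, the gene of ornithine decarboxylase antizyme, had an NIC chain of 825 and 1288 reads, 94.8% and 94.1% of the gene, and its paralog Oaz2 another with 217 and 267 reads, 87.1% and 89.0%. All 4 introns of both chains were annotated, and 3 of 7 Oaz1 transcripts and 2 of 7 Oaz2 transcripts in the annotation contain an intron of 1 to 3 bp, the shortest being 1 bp in both genes. The closest annotated transcript had 1 intron more than the chain in both genes. Whether that is an intron of 1 to 3 bp was not examined, so these 2 chains are not by themselves evidence of separate splice forms. Srd5a2, a steroid 5α-reductase gene, had an NNC chain of 313 and 272 reads (63.0% and 49.2% of the gene; chromosome 17, 74014886 to 74047916), with 4 introns in the annotation and 1 outside it. Cct6a had an NNC chain of 243 and 308 reads. NIC chains stood in Idh3g (216 and 306 reads), Cyb561 (224 and 242 reads, 53.5% and 52.7% of the gene), Phb2 (177 and 275 reads, 96.2% and 92.6%) and Hnrnpk (235 and 202 reads).

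Spike-in RNAs of known sequence gave a measure of models produced outside the annotation for RNA without introns. Of 11058 ERCC reads in replicate 1, 1 lay outside the known class (0.00904%, Clopper-Pearson upper bound 0.0504%), and of 17139 in replicate 2, 0 did, which allows up to 0.0175%. The share among mouse reads was 26.0% (25.9 to 26.1) and 28.1% (28.0 to 28.2), intervals far above those bounds (Fisher's exact test was run within each library). ERCC molecules have no introns, so they do not measure errors at splice sites. By the definitions of the classes, their reads could not form NIC or NNC chains or hold part of an annotated intron chain. ISM, NIC and NNC held 9.09%, 5.45% and 3.99% of mouse reads in replicate 1, and 11.3%, 4.08% and 3.10% in replicate 2. The argument from introns does not cover the single-exon models, which were 10.7% and 15.3% of ISM reads. Most of the difference from mouse reads was therefore set by the design and does not measure artefacts in these classes.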

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

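Single loci outside annotated genes were not described above, where their classes were compared as a whole. The loci with the most reads that were found in both libraries by the same intron chain are given here with their total reads, each above the 3 reads that a count of 0 allows. The comparison of their introns with the annotation, and the single-exon model, were chosen after the results were seen.

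Intergenic locus 1, on chromosome Y (43918755 to 43923547, minus strand), had 122 reads, 110 in replicate 1 and 12 in replicate 2, in a part of the chromosome whose nearest annotated gene is Gm21241 at 28615 bp. Intergenic locus 2 (chromosome 11, 88890249 to 88896412) had 41 reads, 18 and 23 in the libraries. Intergenic locus 3 (chromosome X, 32502591 to 32507553) had 21 reads, 20 and 1. Intergenic locus 4 (chromosome 15, 76559886 to 76566448) had 21 reads, 5 and 16. Intergenic locus 5 (chromosome 4, 3192265 to 3200300) had 19 reads, 10 and 9. None of the introns of these 5 loci was annotated on either strand.

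The antisense locus at Mc2r, the ACTH receptor gene, had 141 reads, 57 and 84, against 30 and 67 reads of Mc2r itself. The locus at Crebbp (chromosome 16, 4128444 to 4213997) had 74 reads, that at Nr2f2 (chromosome 7, 70353074 to 70360593) 56, that at Tspan12 (chromosome 6, 21845796 to 21852169) 53 and that at Mbnl1 (chromosome 3, 60529549 to 60598100) 45. In all 5 of these antisense chains every intron coincided with an annotated intron on the opposite strand (2 of 2 introns at Mc2r, 5 of 5 at Crebbp, 2 of 2 at Nr2f2, and 1 of 1 at Tspan12 and Mbnl1), and none with an annotated intron on their own strand. Their reads are therefore not evidence of separate antisense genes. The single-exon antisense model with the most reads (chromosome 17, 39843013 to 39846245, minus strand, overlapping Gm26917) had 1975 reads in replicate 1 and 5409 in replicate 2, 7.60% and 10.03% of antisense reads.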

How the results depend on the processing

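Leaving out genes over 10-fold different, leaving out the most abundant member of a list and taking chains with exactly 2 to 4 reads were chosen after seeing the data; the other alternatives were planned. Of the values under alternatives, 101 stayed within the spread (for counts, within 1.5 times) and 46 moved. For list sums, class shares and the median leading share, leaving out 1 of the 2 libraries could only count as staying. The tally is therefore not a measure of stability. The gene list sums (steroidogenesis, cholesterol supply, chromaffin, liver and adipocyte) stayed within 1 SD under each alternative run, except that cholesterol supply was 5557 CPM without Apoe, where its direction between libraries turned, and chromaffin 6937 CPM without Chgb, where it did not. But with 2 libraries leaving out either cannot move a mean by more than 1 SD, so this says nothing about stability. Steroidogenesis ranged from 29608 to 69622 CPM between the libraries, cholesterol supply from 8434 to 21244, chromaffin genes from 8764 to 12850, liver from 2.66 to 29162 and adipocyte from 2618 to 3739.

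The correlation of 0.808 fell to 0.603 for genes with at least 10 reads and was 0.904 without genes over 10-fold different. That rise was built in, since those genes were picked by the ratio between these libraries. The 4183 genes called became 1523 with an assumed coefficient of variation of 0.2, which is below the estimated 0.604. With models of at least 2 and at least 5 reads, the known share rose to 78.4% and 83.1%, while NIC was 3.58% and 2.69%, NNC 1.81% and 1.21%, antisense 3.12% and 2.32%, and intergenic 0.300% and 0.211%. ISM (7.09%) and genomic (3.37%) moved at 5 reads. With multi-exon models alone, known was 80.1% (80.001% and 80.148% in the libraries, where the order turned), genomic 0.103%, antisense 0.129% and intergenic 0.0453%, by construction, since these classes are mostly single-exon. Intergenic was 0.523% without genes over 10-fold different.

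Recurrence depended on the read minimum. With at least 1, 5 and 10 reads it was 77.6%, 95.3% and 96.7% for known, 37.1%, 79.6% and 84.7% for ISM, 31.2%, 85.5% and 90.7% for NIC, and 17.0%, 78.5% and 84.6% for NNC chains. With 2 to 4 reads it was 73.1% for known and 55.7% for NIC, and with splice sites within 5 bp 64.9% for NNC. Different isoform use fell from 553 of 3172 genes tested to 89 of 1527 with known transcripts alone and 131 of 2482 without ISM reads. Fewer chains and genes are compared there. The median leading share was 98.9%, 83.8% and 82.1% with known transcripts alone, without ISM reads and with at least 100 reads. Genes under 50% numbered 53 of 4266, 500 of 5142 and 132 of 1407 in these settings, against 971 of 5749. Counted in a single library they numbered 1145 to 1494; without replicate 1 there were 1494. The cause of these moves was not otherwise tested. No paired analysis was possible because there is 1 group. SIRV spike-ins alone gave no value, and ERCC alone is the reported value.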

Other observations

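The test of muscle transcripts was chosen after the pattern was seen, and so were the genes in the next paragraph and the read minimums for spike-ins; the other tests below were written before their results were seen.

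Single long non-coding RNAs, taken without a list or a test of the class, went both ways between the libraries. Malat1, a nuclear-retained RNA abundant in most tissues, had 44 reads in replicate 1 and 2980 in replicate 2, or 58.5 and 2461 CPM, a log2 ratio of 5.38 ± 0.22 (counting SE). Neat1, the scaffold of nuclear paraspeckles and a neighbour of Malat1 on chromosome 19, differed less, with 171 and 230 CPM and a log2 ratio of 0.42 ± 0.15. Meg3, an imprinted RNA, had 66.5 and 296 CPM (log2 ratio 2.14 ± 0.22), while its imprinted neighbour Dlk1 was lower in replicate 2 at -0.94 ± 0.12. H19, another imprinted RNA, was lower in replicate 2, with 20 and 2 reads. Hsd11b1, which regenerates active glucocorticoid and which liver also expresses, had 136 and 489 CPM.

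Liver transcripts in replicate 2 covered much more than the genes named above. Of 40 further abundant liver transcripts listed before the test, 97.5% (39 of 40) were at 10 CPM or more in replicate 2 and at least 10-fold above replicate 1, among them Serpinc1 (1776 CPM) and Hpx (1629 CPM); 12 of the 40 were detected in replicate 1, 3 of them at 10 CPM or more. Misassignment to partial models is argued against by the 79.5% of liver-list reads (95% Clopper-Pearson interval 79.12 to 79.96) that lay in annotated multi-exon transcripts, a share that does not bear on misassignment between paralogs, which the test had first been meant to cover. RNA of liver cells in the library may therefore account for the pattern, but whether it entered with the tissue or later was not tested. No biological explanation was tested, since the design has 1 group.

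Skeletal muscle transcripts in replicate 1 formed a second set. Of 28 listed, 85.7% (24 of 28) were at 10 CPM or more there, and 19 of 23 when the 5 genes that had shown the pattern were left out; the list summed to 5137 CPM in replicate 1 and 81.8 CPM in replicate 2, with 5 members detected in replicate 2, 2 of them at 10 CPM or more. All 21 tested members were lower in replicate 2 (21 adjusted over the list alone). The most abundant were Atp2a1 (1552 CPM), Acta1 (1209 CPM) and Ckm (849 CPM). RNA of skeletal muscle in replicate 1 is a candidate explanation, and how it entered was not tested, nor was a biological explanation.

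Replicate 2 had a larger share of reads outside the known class, by 2.11 percentage points. With multi-exon models alone the known share was 80.001% in replicate 1 and 80.148% in replicate 2, so the gap was not seen there. The multi-exon classes still differed in opposite directions. ISM was higher in replicate 2 (9.11% and 11.2%), while NIC (6.12% and 4.76%) and NNC (4.49% and 3.62%) were lower. Reads of genes at least 10-fold higher in replicate 2 are argued against as the source of the gap. Without these genes and the loci antisense to them it was 4.28 points, 203% of the full gap. The prediction was written for reads of liver genes, but this set was picked by the ratio between these libraries. It also took out genes such as Malat1 and left in genes with smaller differences, such as Hsd11b1. The test therefore cannot exclude RNA from liver as a source. Loss of long molecules remains open, since over 49 spike-ins of 274 to 1994 bp, the log2 ratio of replicate 2 to replicate 1 had a Spearman correlation of -0.24 with length (permutation p = 0.0957), between the bounds set beforehand, which were -0.4 for and -0.2 against this explanation. Over 6 other read minimums it ranged from -0.41 to -0.18, with 1 under the lower and 1 above the upper bound. The spike-ins are shorter than the mean transcript model in the libraries (2604 and 2194 bp), so loss of longer RNA could go unseen, and no biological explanation was tested.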
